A study of Wolfiporia cocos with 12 samples.

How the data were processed

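Wolfiporia cocos strain MD-104 is a basidiomycete that causes brown rot, a decay in which cellulose and hemicellulose are removed from wood and most lignin is left in modified form. Per the labels' protocols, the fungus was grown in triplicate cultures of 250 ml on a rotary shaker for 5 days, and the medium held 1 of 4 carbon sources. These were glucose, Avicel (a microcrystalline cellulose), ground wood of bigtooth aspen (Populus grandidentata) at 0.5% w/v, and ground wood of lodgepole pine (Pinus contorta) at 0.5% w/v. Poly-A RNA was converted to libraries from 1 µg of total RNA and sequenced as single reads of 100 nt. The 12 libraries comprised 3 per carbon source. Glucose and Avicel libraries were sequenced on lane 1 and the aspen and pine libraries on lane 2, per the labels. Lane and wood against defined medium therefore cannot be told apart, whereas Avicel against glucose and pine against aspen each lie within a single lane.

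The deposited table held 12746 gene models on 225 scaffolds, with a protein ID, an InterPro label for 7089 models and scaffold coordinates. The values of each library were taken as RPKM (reads per kilobase of model per 1e6 reads), deposited by the authors. No header names that unit, and it was inferred from the values. CASAVA 1.8.2 is named in the submitters' processing notes. The aligner, the counting tool and the genome build are not given in the sources used here, and no reference genome was used, so coordinates are those of the deposited table and no exon, intron or UTR is stated. Whether reads were counted by strand is not given either, so overlapping models can share reads. The authors also deposited group means, ratios to glucose and p-values for 4 comparisons. Their group means equalled the geometric mean of the values above 0 in each group, within a difference of 0.002. The emPAI scores and peptide numbers from mass spectrometry were deposited by the authors as 1 value per carbon source. The emPAI score rises with the number of peptides observed for a protein, and the 4 columns have the same sum, so they were scaled to each other in a way that is not given in the sources used here. Signal peptide probabilities, as a fraction from 0 to 1, were deposited by the authors for 1041 models. No column of per-sample values was left unmapped.

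Depth was recovered from the spacing of low values, because a whole read is worth a fixed RPKM step for a model of given length. Of 2298 models with low values, 711 showed a common step in several libraries and 151 of these gave the same most frequent set of depths. The relative depths translate to 15.3 to 23.2, in units of 1e6 reads per library, if RPKM was scaled per 1e6 reads. A count of 3 reads in a model of 1 kb then equals 0.13 to 0.2 RPKM, which is the level below which a value of 0 says little. This floor covers counting error only. Per library, 1532 to 1891 models were listed at 0, and 1087 were listed at 0 in all 12. Replicates were compared before averaging. The squared difference between replicates of a group was 13.8 to 43.7 times the counting noise, so no library was a repeat deposit of another.

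The main test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with all 4 groups in a single linear model, contrasts between groups, and empirical Bayes moderation with an intensity trend. Models with a group mean of at least 1 RPKM in at least 1 group were tested, which left 10184. The fit had 8 residual degrees of freedom, and the prior added 3.6. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison together with a fold of at least 2. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Values are given as mean ± SD over 3 cultures, and each log2 change carries its standard error (SE). An F test asked whether a gene differed among the 4 carbon sources, at an adjusted p under 0.05 with no fold threshold. On simulated data built from the real means and spreads, 86% to 100% of 50 genes changed by a log2 size of 1.5 to 4 were recovered in each of the 6 comparisons, with 3 to 7 false calls among 10184 genes. All sizes were planted together, with independent normal noise of the moderated spread. More changed genes ease the adjusted p, so this recovery does not carry over to pine against aspen, where 16 genes were called.

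The groups, tests, alternatives, 26 gene lists and the rule for naming genes were fixed before the data were examined. The design allowed for counts, linear normalized values or log values, and the test for linear normalized values applied. Lists were defined by words in the InterPro labels. List names are short forms for these labels, which give a family or fold and do not settle the activity of a member. After reading the labels, and without reference to expression, members matched by an unrelated label were removed. These were 6 phosphatases from the peroxidases, 2 nucleotide-sugar carriers from the sugar transporters, 98 F-box, retroelement and exonuclease models from DNA replication, 187 zinc fingers of other kinds from the transcription factors, and 6 lipid transfer or tRNA enzymes from terpenoid synthesis. The named genes were, in each comparison with glucose and in pine against aspen, the 5 annotated genes with the largest rise and the 5 with the largest fall whose replicate values did not overlap. Up to 3 called members of each list with the largest change were added, together with the gene of largest rise and of largest fall whatever its annotation. For each wood against Avicel the rule took 3 each way and the largest in each direction. It gave 123 models, and genes outside it are marked as chosen after their values were seen. A gene is written as its label followed by its protein ID.

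Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over 144 pairs of list and comparison, and again with camera at an estimated correlation and with fry. Beside each count over all genes, a count with p adjusted over the list alone was made. Enrichment of InterPro families among called genes was tested with a one-sided Fisher exact test over 269 families with at least 5 tested members, against 6437 tested models with a label. It was adjusted over 3228 tests, of which 43 passed. This family analysis had no list fixed in advance. Overlaps between comparisons with glucose were set beside 100 simulations of unchanged groups against the same glucose libraries and beside the overlap of independent lists. The cultures are separate per the labels, and nothing in the labels pairs equal replicate numbers.

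Alternatives were pseudocounts of 0.1 and 5, no filter and a minimum of 10 RPKM, median centring, quantile normalization, moderation without a trend, fits of only the 2 groups compared, a replicate block, no fold threshold, a fold threshold of 4, and each of the 12 libraries left out in turn. Counts of called list members without each library were added after seeing the data. Other tools were Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.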

Results

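Transcript levels of Wolfiporia cocos were measured in 12 cultures, 3 each on glucose, Avicel, ground aspen and ground lodgepole pine, after 5 days. The series concerns gene expression early in the attack on wood, and the glucose cultures serve as the reference medium. Depth, in units of 1e6 reads, was 17.3 to 21.3 for glucose, 15.3 to 19.6 for Avicel, 15.4 to 23.2 for aspen and 17.3 to 22.3 for pine, as recovered from the spacing of low values. The median model stood at 9.9 to 12.7 RPKM per library. The 10 most abundant models took 12.3% to 18.3% of all RPKM in the Avicel libraries and 9.16% to 14.9% in the others. Replicates of a group correlated across genes at r = 0.976 to 0.991 on the log2 scale, where genes are not independent replicates.

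Glucose, Avicel and the 2 woods together separated along the first axis of variation, on which aspen and pine overlapped. The first principal component held 56.4% of the variance and ran from the glucose libraries at -47.48 to -43.89, through Avicel at -35.68 to -18.51, to the wood libraries at 30.69 to 50.39. The widest gap, between Avicel and wood, is also the gap between the lanes. The second held 11.2%, and Avicel replicate 3 lay farthest along it at -41.13. Of 10184 tested genes, 2987 (29.3%) differed among the 4 carbon sources in the limma F test at an adjusted p under 0.05, which carries no fold threshold.

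**Figure D1:**
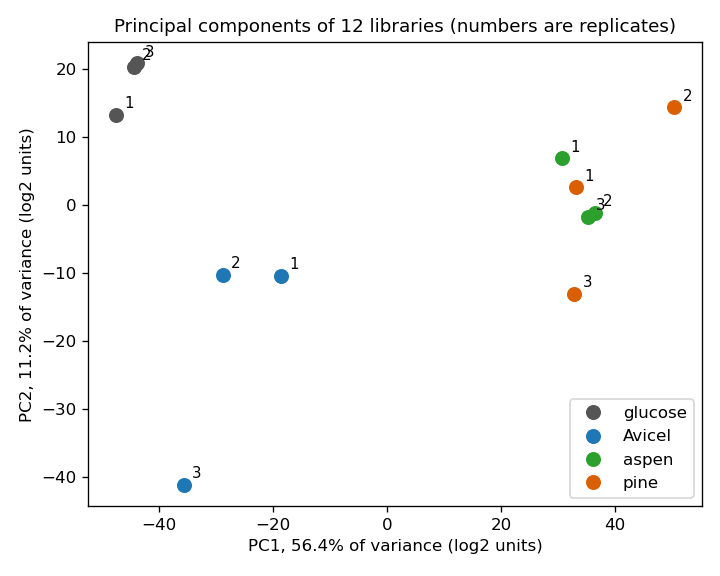
Principal components of log2(RPKM + 1) for the 12 libraries, with PC1 (56.4% of variance) on the x axis and PC2 (11.2%) on the y axis, both in log2 units, coloured by carbon source and numbered by replicate. Glucose libraries lie at the left, Avicel libraries between -35.68 and -18.51 on PC1, and aspen and pine libraries together at the right.

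Growth on Avicel, against glucose, raised transcripts of some enzymes that act on plant and fungal wall polymers and of some sugar transporters. Among called genes with an annotation the largest rise was in glycoside hydrolase family 10 (GH10) 164484, a family of endoxylanases, from 32.4 ± 6.24 to 953 ± 787 RPKM (log2 change 4.22, SE 0.79, limma adjusted p = 0.0174). GH18 chitinase 146767 rose from 126 ± 50.6 to 1210 ± 123 RPKM, cerato-platanin 72733, a small secreted cysteine-rich protein, from 7.21 ± 3.9 to 78.5 ± 28.7, and sugar transporter 102298 from 4.96 ± 0.434 to 51.2 ± 10.5. Pyridoxal phosphate-dependent decarboxylase 107956 fell from 52.6 ± 32.6 to 3.61 ± 1.6 RPKM, and aldo/keto reductase 28055 from 442 ± 48.2 to 53.2 ± 10.7. The question is which genes respond to crystalline cellulose, and both groups were sequenced on the same lane.

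In all, 170 genes were called, 98 higher and 72 lower on Avicel, of which 39 changed at least 4-fold. The median log2 change over all genes was -0.17 as deposited and near 0 after median centring, so small negative changes are read against that shift. With median centring 116 genes were higher and 42 lower, and with quantile normalization 98 and 47. The balance turned without a fold threshold (123 and 192) and without Avicel replicate 2 (88 and 102), and was even without glucose replicate 3 (54 and 54). The largest called rise without an InterPro label was in 167658, the most abundant transcript on Avicel among the named genes, at 1685 ± 1510 RPKM on glucose and 26220 ± 13900 on Avicel (log2 change 4.24, SE 0.84, adjusted p = 0.0205). This call was lost without glucose replicate 1 or 3 or Avicel replicate 1 or 3 (highest adjusted p = 0.0746). The largest fall was in unlabelled 146011, from 99.9 ± 63.1 to 5.99 ± 4.93 RPKM (log2 change -3.91, SE 0.51, adjusted p = 0.00256). That gene lies on scaffold 13 at 864191 to 865114, close to decarboxylase 107956 at 859021 to 862784. Ricin B-related lectin 19493 fell by 2.53 on the log2 scale (SE 0.36, adjusted p = 0.00465), and this family, of carbohydrate-binding domains, had 3 of 10 tested members lower where chance gives 0.07 (Fisher adjusted p = 0.00661).

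Among hemicellulases, which act on xylan and related polymers, 4 of 14 tested members rose and 10 did not pass (5 with p adjusted over the list alone; camera adjusted p = 2.9e-09, and adjusted p = 0.173 with an estimated correlation). They included arabinofuranosidases 19345 (log2 change 2.15, SE 0.5) and 77451 (1.32, SE 0.25), which lie close together on scaffold 9 at 1961591 to 1965069 and 1957526 to 1960466. Of 26 sugar transporters 5 rose and 21 did not pass, also 5 adjusted over the list alone (camera adjusted p = 0.000139, and adjusted p = 0.173 with an estimated correlation), among them 25027 and 104972 with log2 changes of 1.75 and 1.27. Of 24 enzymes acting on chitin and beta-1,3-glucan of fungal walls 5 rose, also 5 adjusted over the list alone, including GH18 models 165069 (2.51, SE 0.43) and 89691 (1.83, SE 0.25). Their camera adjusted p was 0.00371, with adjusted p = 0.253 with an estimated correlation, and the list's median was -0.10 while its mean was 0.29. Of 24 cellulases and wall-loosening proteins 2 rose, the GH5 models 139561 (2.83, SE 0.46) and 101537 (1.07, SE 0.19), and also 2 adjusted over the list alone. The camera adjusted p was 0.00367 upward, with adjusted p = 0.2997 with an estimated correlation, although the median was -0.09 against a mean of 0.39. Glutathione S-transferases 139753 and 22163 fell by 2.07 and 1.25, as 2 of 26 members (3 adjusted over the list alone; camera adjusted p = 0.0276, and adjusted p = 0.479 with an estimated correlation).

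The call on GH10 164484 was lost without any 1 of the glucose replicates or without Avicel replicate 3 (highest adjusted p = 0.0632). The number of called genes was 109, 93 and 108 without glucose replicates 1, 2 and 3, and the called hemicellulases numbered 1, 2 and 0 without these and 2 and 1 without Avicel replicates 2 and 3. Called sugar transporters numbered 2 without glucose replicate 2 and 3 without glucose replicate 1 or 3, Avicel replicate 1 or 2, or aspen replicate 3, and called fungal wall enzymes 3 without glucose replicate 3. Called cellulases and wall-loosening proteins numbered 1 without glucose replicate 2 or Avicel replicate 2 and 5 without Avicel replicate 1. Single calls were also lost for arabinofuranosidase 77451 (without glucose replicate 1 or 3 or Avicel replicate 3, highest adjusted p = 0.0684) and for 19345 (without any 1 glucose or Avicel library, aspen replicate 1 or pine replicate 1, highest adjusted p = 0.133). Sugar transporter 104972 lost its call without glucose replicate 2 or Avicel replicate 1 (highest adjusted p = 0.0771), and GH5 101537 without glucose replicate 2 or Avicel replicate 2 (lowest log2 change 0.95). A pseudocount of 5 ended the call on 101537, no filter that on 19345, and a fit of only the 2 groups that on glutathione S-transferase 139753.

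Smaller movements on Avicel were these. Of 181 cytochrome P450 genes 4 rose, 138085 among them (log2 change 2.34, SE 0.35), and 3 fell, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.002, and adjusted p = 0.630 with an estimated correlation), with a list median of -0.06 and a mean of 0.06. After median centring 6 rose and none fell. The total of 7 was 3, 2, 2 and 4 without glucose replicate 1, glucose replicate 2, Avicel replicate 1 and Avicel replicate 3, and 3, 4 and 4 without aspen replicates 1, 2 and 3. No fall was called in these, save 1 without glucose replicate 1, nor without glucose replicate 3 (6 higher) or pine replicate 3 (5 higher). Without Avicel replicate 2, 4 rose and 5 fell. Of 9 beta-glucosidases limma called none, where 5 had an unadjusted p under 0.05 and 2 rose adjusted over the list alone (camera adjusted p = 2.19e-05, and adjusted p = 0.173 with an estimated correlation). GH3 29607, chosen after its values were seen, had a limma adjusted p of 0.0108 but missed the fold threshold (log2 change 0.77). Leaving out 1 library gave up to 2 beta-glucosidases called higher. Of 5 chloroperoxidases limma called none, where 2 had an unadjusted p under 0.05 (camera adjusted p = 0.00367 upward, and adjusted p = 0.184 with an estimated correlation). Model 23619 is labelled isocitrate lyase and phosphorylmutase, a label that does not single out isocitrate lyase of the glyoxylate cycle. It rose from 220 ± 59.3 to 439 ± 20.4 RPKM as 1 of 5 members of the oxalate and glyoxylate list (camera adjusted p = 0.0276, and adjusted p = 0.493 with an estimated correlation). This call was lost without glucose replicate 2 or 3 or Avicel replicate 1 (highest adjusted p = 0.0573), with quantile normalization and with only the 2 groups in the fit. Of 17 pectinase list members 1 rose, pectin lyase fold protein 23116, or 3 adjusted over the list alone (camera adjusted p = 0.0276, and adjusted p = 0.602 with an estimated correlation), with a median of -0.06 and a mean of 0.21. None of these 17 was called without glucose replicate 2 or 3, any 1 Avicel library, aspen replicate 1 or 3 or pine replicate 1, and 2 and 3 were called without aspen replicate 2 and pine replicate 2. HSP20-like chaperone 85445 fell by 1.49 (SE 0.2, and not called with a pseudocount of 5) as 1 of 73 heat shock genes, whose list was placed upward by camera (adjusted p = 0.0445, and adjusted p = 0.765 with an estimated correlation) at a median of -0.11 and a mean of 0.01. The called number was 2 and 3 without Avicel replicates 1 and 2. Of 233 peptidases 2 rose, both of family A1. These became 0 higher and 1 lower and 1 and 1 without glucose replicates 2 and 3, and 7 and 0 and 4 and 1 without Avicel replicates 1 and 2. Among 11 iron genes and 5 multicopper oxidases limma called none, where 1 and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.0760 and 0.509). For the iron genes, up to 1 was called higher with a library left out or under another planned setting.

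Growth on aspen wood changed 1202 genes against glucose, 534 higher and 668 lower. That balance depends on scaling and threshold, with 1021 higher and 1668 lower without a fold threshold, 605 higher and 566 lower after median centring, 613 and 562 after quantile normalization, and 183 and 181 at a fold of 4. Cerato-platanin 72733 (scaffold 5, 2697894 to 2698465) showed the largest rise of any gene, from 7.21 ± 3.9 RPKM to between 3320 and 5091 in the 3 aspen cultures (log2 change 9.12, SE 0.35, adjusted p = 1.64e-08). Sugar transporter 102298 on the same scaffold, at 2741525 to 2744358, rose to 835 ± 226 RPKM (log2 change 7.10, SE 0.22), WSC carbohydrate-binding protein 106250 from 4.66 ± 1 to 373 ± 25.3 (6.06, SE 0.19), and ferric reductase 109665, of a family that reduces iron at the membrane, from 9.46 ± 2.59 to 560 ± 423 (5.45, SE 0.92). The deepest fall was in unlabelled 144582, from 560 ± 164 to 6.14 ± 3.24 RPKM (-6.39, SE 0.42), followed among annotated genes by NmrA-like 133337, from 110 ± 20.3 to 1.06 ± 0.29 (-5.75, SE 0.41). The comparison asks what changes on a hardwood, and the 2 groups were on different lanes, so lane and medium cannot be told apart within it.

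Many transport genes rose. Of 26 sugar transporters 10 rose, 16 did not pass and none fell (10 adjusted over the list alone; camera adjusted p = 3.12e-07, and adjusted p = 0.153 with an estimated correlation), with 25027 and 27321 at log2 changes of 4.34 and 2.93. In the wider major facilitator family, of membrane transporters, 27 of 108 members rose where chance gives 5.96 (Fisher adjusted p = 1.49e-08), among them 127030 with 5.28 ± 1 RPKM on glucose and 261 ± 43.9 on aspen. Of 15 oligopeptide transporters 8 rose (chance 0.83, adjusted p = 0.000146), and of 7 cerato-platanins 4 (chance 0.39, adjusted p = 0.0257).

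Wall-degrading enzymes moved in different directions. Beta-glucosidases release glucose from short cellulose fragments, and that list holds GH1 and GH3 models, whose labels do not give the activity. Of 9 tested members 5 rose and 4 did not pass (also 5 adjusted over the list alone, camera adjusted p = 5.98e-05, and adjusted p = 0.173 with an estimated correlation). GH3 137577 rose from 4.49 ± 0.49 to 31.6 ± 7.32 RPKM. Without glucose replicate 3 or aspen replicate 2, the called beta-glucosidases numbered 3. Of 14 hemicellulases 6 rose, also 6 adjusted over the list alone, led by GH10 164484 at 949 ± 504 RPKM (log2 change 4.70; camera adjusted p = 0.00741, and adjusted p = 0.597 with an estimated correlation). Of 17 members of the pectinase list 3 rose, also 3 adjusted over the list alone (camera adjusted p = 0.0277, and adjusted p = 0.602 with an estimated correlation). The 3 were GH28 128405 (4.20, SE 0.4), pectinesterase 165643 (3.06, SE 0.3) and pectin lyase fold protein 23116 (1.51, SE 0.27), and 5 were called without Avicel replicate 1 or pine replicate 2. The label of 23116 gives a fold and does not show that it acts on pectin. Among 24 members of the cellulase and wall-loosening list 5 rose and 4 fell (camera adjusted p = 0.876, with 5 and 4 adjusted over the list alone). The list takes GH5 models by their label, which does not show that a member acts on cellulose. GH5 139561 rose from 4.9 ± 1.37 to 133 ± 59.4 RPKM, and GH12 24190, of an endoglucanase family, fell from 218 ± 96.6 to 8.1 ± 3.08 RPKM (-4.53, SE 1.04, adjusted p = 0.00816). GH5 141870 fell by 3.21 (SE 0.99, adjusted p = 0.0329), a call lost without any 1 of the glucose or aspen libraries (highest adjusted p = 0.112). Its SE pools the spread of all 4 groups, and its Avicel values ran from 95.8 to 2397 RPKM. Its glucose values, 104.1 to 220.6 RPKM, did not overlap its aspen values, 7.31 to 26.01 RPKM. Without glucose replicates 1, 2 and 3 the called members of this list were 2 higher and 3 lower, 4 and 2, and 3 and 3. Without aspen replicates 2 and 3 they were 3 and 2, and 5 and 2. GH61 134838, of the lytic polysaccharide monooxygenases, rose by 1.52 (SE 0.28). The other tested member of that list, 57339 (chosen after its values were seen), had a change of 0.42 (adjusted p = 0.13).

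Iron and copper enzymes rose in part. Of 11 iron reduction and uptake genes 3 rose (also 3 adjusted over the list alone), namely ferric reductases 109665 and 140747 (log2 change 1.74, SE 0.19) and iron permease FTR1 139155 (2.35, SE 0.38). The camera adjusted p was 0.0231, with adjusted p = 0.2997 with an estimated correlation. Of 5 multicopper oxidases, the tested members of the laccase list, 3 rose (also 3 adjusted over the list alone, camera adjusted p = 0.0164, and adjusted p = 0.173 with an estimated correlation). These were 157228 (3.72, SE 0.56), 165246 (2.34, SE 0.55) and 123970 (1.84, SE 0.51), the last lost without glucose replicate 3 or aspen replicate 2 (highest adjusted p = 0.0807). FTR1 139155 and multicopper oxidase 123970 overlap on scaffold 9, at 391870 to 396926 and 394343 to 397155, so reads may have been shared and both values are uncertain. Fungal wall enzymes gained 6 of 24 members, also 6 adjusted over the list alone, including GH18 146767 at 2672 ± 209 RPKM and chitinase 76203 from 1120 ± 247 to 5861 ± 316. Their camera adjusted p was 0.00103, with adjusted p = 0.188 with an estimated correlation.

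Some genes of central carbon metabolism and detoxification were lower on aspen. Of 47 glycolysis and TCA cycle genes 9 fell and none rose (also 9 adjusted over the list alone; camera adjusted p = 0.0456, and adjusted p = 0.766 with an estimated correlation), among them phosphoglycerate mutase 136599 (-1.65, SE 0.19), enolase 22675 (-1.41, SE 0.27) and pyruvate kinase 147935, from 2230 ± 233 to 862 ± 257 RPKM. Of 26 glutathione S-transferases 6 fell, also 6 adjusted over the list alone (camera adjusted p = 0.314), the deepest being 83420 with 30.3 ± 11.7 RPKM on glucose and 0.365 ± 0.0405 on aspen. Catalase 84844, which removes hydrogen peroxide, fell from 3103 ± 987 to 328 ± 6.41 RPKM, with 3 of 28 antioxidant genes lower, also 3 adjusted over the list alone, and 5 without glucose replicate 3. Of 189 transcription factors 5 rose and 10 fell (5 and 9 adjusted over the list alone, 7 and 8 after median centring, 3 and 8 without aspen replicate 2, and 3 and 9 without aspen replicate 3). They included C2H2 zinc fingers 124482 (-5.24, SE 0.7) and 50037 (-4.10, SE 0.64) and GATA factor 133057 (-2.31, SE 0.43). Of 181 cytochrome P450 genes, monooxygenases of many substrates, 22 rose and 23 fell (22 and 24 adjusted over the list alone, and 25 and 20 after median centring). Planned settings of pseudocount, filter, scaling, moderation and block gave 19 to 25 higher and 14 to 29 lower. The largest rises were in 138085 (4.45, SE 0.35), 75851 and 90431. The last 2 are adjoining models on scaffold 7, at 1232403 to 1232660 and 1232723 to 1234356. Of 233 peptidases 12 rose and 14 fell (12 and 14 adjusted over the list alone, and 14 and 12 after median centring), and aspartic peptidases 22529 and 88607 fell from 850 ± 260 to 75.3 ± 28.5 RPKM and from 5068 ± 855 to 707 ± 261. Caspase-like C14 peptidases were lower for 6 of 15 members (chance 0.86, Fisher adjusted p = 0.012), led by 166137 (-3.08, SE 0.57).

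The remaining lists had few called members on aspen. The heat shock list, which also holds heat shock factor-type DNA-binding protein 100521, had 4 of 73 members lower, Hsp20 25530 and 22711 among them (2 adjusted over the list alone). In that list 1 was called without glucose replicate 1 or aspen replicate 1 and 2 without glucose replicate 2 or after median centring. The call on 22711 was lost without glucose replicate 1 (adjusted p = 0.0509) and that on 25530 without glucose replicate 1 or 2 or aspen replicate 1 or 2 (highest adjusted p = 0.113). Ribosomal proteins had 1 of 117 members lower, L49/IMG2 130801 (-1.09, and -0.96 without glucose replicate 1), a call also lost after median centring and with a pseudocount of 5, with a list median of -0.35 (none adjusted over the list alone; camera adjusted p = 0.00103, and adjusted p = 0.785 with an estimated correlation). In terpenoid and sterol synthesis 3 of 34 members rose and 2 fell, and in lipases and fatty acid oxidation 3 of 27 rose and 2 fell, with the same counts adjusted over the list alone. Without glucose replicate 2, 2 terpenoid genes rose and 1 fell, and 3 rose and 1 fell without glucose replicate 3 or aspen replicate 1 or 2. Lipase genes were 2 higher and 1 lower without glucose replicate 1 or 2 or any 1 aspen library. Peroxide-generating oxidases had 1 of 17 higher and 3 lower. These became 1 and 0 without glucose replicate 1 or 2, 0 and 1 without aspen replicate 1, 1 and 1 without aspen replicate 2, and 2 and 3 without pine replicate 3. After median centring these were 2 higher and 1 lower. Of 5 chloroperoxidases, the tested members of the peroxidase list, 127790 rose by 1.09 (SE 0.34, adjusted p = 0.033), a call lost without glucose replicate 1 or 2 or aspen replicate 2 or 3 (highest adjusted p = 0.124). Of the 5, 2 were called without glucose replicate 3 or Avicel replicate 3. With a pseudocount of 5 neither 127790 nor proteasome subunit 110100 was called. Cyclin-like 163204 rose by 2.69 (SE 0.27) as 1 of 2 higher among 43 replication and cell cycle genes. Proteasome subunit 110100 fell by 1.20 as 1 of 33, a call lost without glucose replicate 1 or 2 or aspen replicate 2 or 3 (highest adjusted p = 0.0768). No respiratory chain gene among 25 and no oxalate or glyoxylate gene among 5 was called by limma on aspen, where 8 and 2 had an unadjusted p under 0.05. Respiratory chain genes 120742 (-0.71, limma adjusted p = 0.00469), 152440 (-0.43, 0.0391) and 139452 (-0.42, 0.0411) missed only the fold threshold. They were chosen after their values were seen.

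**Figure D2:**
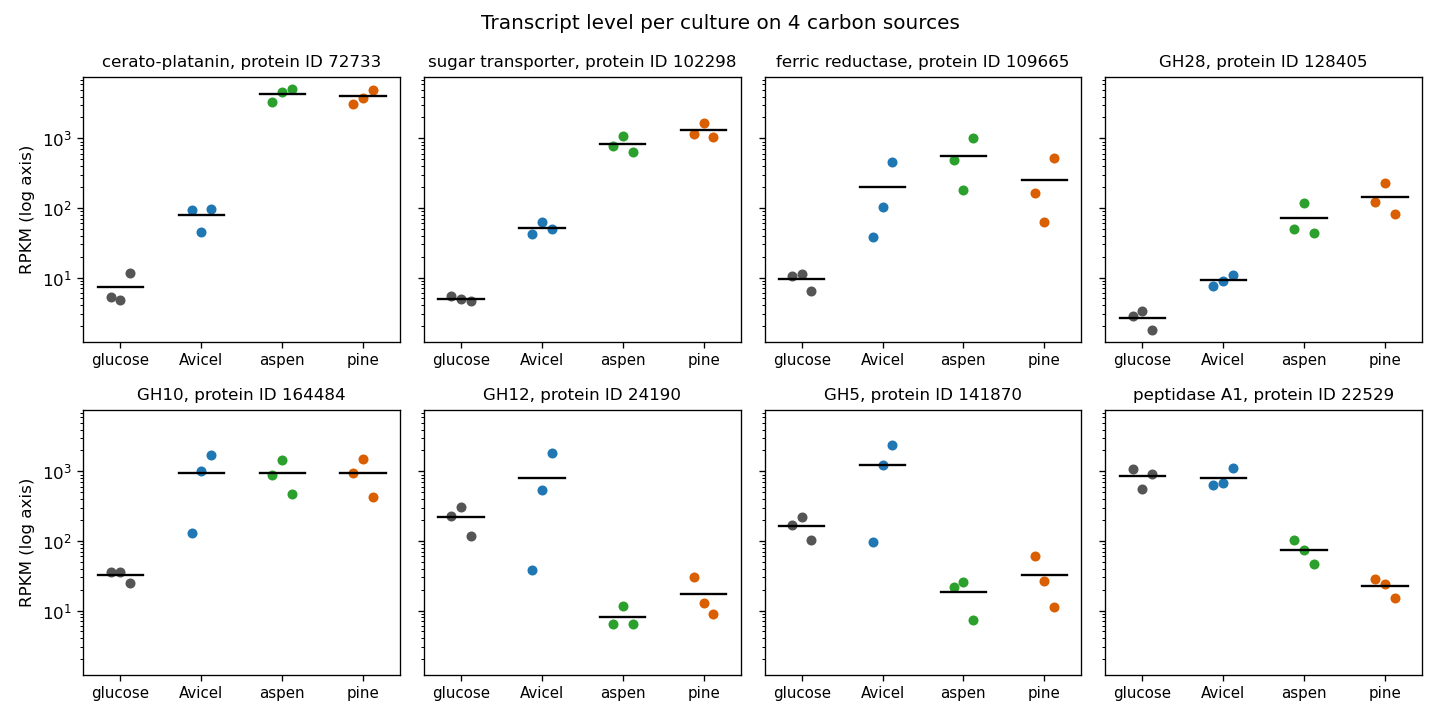
RPKM per culture (dots, log axis) and mean of 3 cultures (bar) for 8 named genes on glucose, Avicel, aspen and pine. Cerato-platanin 72733, sugar transporter 102298 and GH28 128405 stand higher on both woods than on glucose in every culture, GH12 24190 and peptidase A1 22529 stand lower, and GH5 141870 on Avicel spreads from 95.8 to 2397 RPKM.

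Growth on pine wood also changed 1202 genes against glucose, 571 higher and 631 lower, of which 403 changed at least 4-fold (364 on aspen). The balance turned after median centring (647 and 530), after quantile normalization (657 and 540), at a fold of 4 (235 and 168), with a pseudocount of 5 (440 and 410) and without glucose replicate 1 (554 and 551) or pine replicate 2 (567 and 506). Without a fold threshold it lay further down (1019 and 1717). Cerato-platanin 72733 reached 4010 ± 945 RPKM (adjusted p = 2.22e-08) and sugar transporter 102298 reached 1305 ± 334 (7.75, SE 0.22). General substrate transporter 107257 rose from 6.45 ± 1.22 to 622 ± 259 RPKM (6.32, SE 0.28), WSC protein 106250 by 5.94 (SE 0.19) and cytochrome P450 24176 from 1.73 ± 0.35 to 178 ± 104 RPKM (5.89, SE 0.51). The deepest falls were in 144582 (-6.05, SE 0.42) and NmrA-like 133337 (-5.83, SE 0.41). They were followed, among genes with an annotation, by phosphopantetheine attachment site protein 140704, from 678 ± 149 to 20.6 ± 14.4 RPKM, and peptidase A1 22529, from 850 ± 260 to 22.5 ± 6.8. Here too the lanes differ, and the comparison asks what changes on a softwood.

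Pectinases and beta-glucosidases had more called members on pine than on aspen, and these counts were not tested against each other. Compared directly, pine and aspen differed by a call at 1 of 17 pectinases and at none of 9 beta-glucosidases. Of 17 pectinases 9 rose and 1 fell (9 and 1 adjusted over the list alone; camera adjusted p = 3.01e-05, and adjusted p = 0.248 with an estimated correlation). GH28 128405 rose from 2.63 ± 0.773 to 142 ± 74.8 RPKM, pectinesterase 165643 from 0.902 ± 0.316 to 42 ± 15.1, and GH28 125762 from 2.77 ± 0.297 to 36.8 ± 31.9. Of 9 beta-glucosidases 7 rose, also 7 adjusted over the list alone, GH3 137577 and 23559 by 3.65 (SE 0.42) and 2.04 (SE 0.35) and GH1 78411 by 1.96 (SE 0.36). The camera adjusted p was 3.71e-07, with adjusted p = 0.153 with an estimated correlation. Of 26 sugar transporters 12 rose, also 12 adjusted over the list alone (camera adjusted p = 2.75e-09, and adjusted p = 0.153 with an estimated correlation). Of 14 hemicellulases 6 rose, also 6 adjusted over the list alone, GH2 24785 from 30 ± 5.35 to 164 ± 12.8 RPKM (camera adjusted p = 0.000139, and adjusted p = 0.367 with an estimated correlation). Of 24 cellulases and wall-loosening proteins 5 rose and 3 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.687). GH5 139561 and its neighbour GH5 106510 (scaffold 10, 1192482 to 1194538 and 1194905 to 1197031) rose by 5.53 (SE 0.46) and 3.02 (SE 0.62). GH12 24190 fell by 3.64 (SE 1.04, adjusted p = 0.0236), a call lost without glucose replicate 1 or 2 or pine replicate 2 or 3 (highest adjusted p = 0.0727). The SE again pools all 4 groups, with Avicel values from 38.5 to 1809 RPKM. Glucose values, 116.95 to 309.37 RPKM, did not overlap pine values, 9.04 to 30.26 RPKM. GH61 134838 rose by 1.26 (SE 0.28), and by 1.00 without pine replicate 1, where its fold was just under the threshold.

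Iron uptake genes 109665 (4.11, SE 0.92), 139155 (2.08, SE 0.38) and 140747 (1.34, SE 0.19) rose as 3 of 11, also 3 adjusted over the list alone, although the list's camera adjusted p was 0.0581. Multicopper oxidases 157228 (4.66, SE 0.56), 165246 (2.08, SE 0.55) and 123970 (1.77, SE 0.51) rose as 3 of 5, also 3 adjusted over the list alone (camera adjusted p = 0.0164, and adjusted p = 0.173 with an estimated correlation), and 1 was called without glucose replicate 3. The call on 165246 was also lost without pine replicate 3 (adjusted p = 0.0518) and that on 123970 without glucose replicate 1 or pine replicate 1 (highest adjusted p = 0.0841). Fungal wall enzymes gained 6 of 24, also 6 adjusted over the list alone (camera adjusted p = 0.0184, and adjusted p = 0.344 with an estimated correlation). The major facilitator family had 26 of 108 members higher (chance 6.29, Fisher adjusted p = 2.29e-07), oligopeptide transporters 7 of 15 (chance 0.87, adjusted p = 0.00186) and GH28 6 of 9 (chance 0.52, adjusted p = 0.000731). Lower families were C14 peptidases with 6 of 15 (chance 0.8, adjusted p = 0.00955), ricin B-related lectins with 5 of 10 (chance 0.53, adjusted p = 0.0102) and leucine-rich repeat proteins with 5 of 10 (chance 0.53, adjusted p = 0.0102).

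Of 117 ribosomal proteins 7 fell (8 adjusted over the list alone), among them L15e 22125 (-1.14, SE 0.32) and L5 28524 (-1.08, SE 0.27), and the list median was -0.56 (camera adjusted p = 1.49e-06, and adjusted p = 0.765 with an estimated correlation). None was called without glucose replicate 1 or pine replicate 2, 2 without glucose replicate 3, 16 without pine replicate 1, and 1 after median centring. The call on 28524 was among those lost after median centring, and that on 22125 among those lost without glucose replicate 3 (adjusted p = 0.0651). Glycolysis and TCA cycle genes were lower for 6 of 47 (7 adjusted over the list alone; camera adjusted p = 0.0576), with 4 called without glucose replicate 1 or pine replicate 2. Phosphofructokinase 25177 was among the 6, a call lost without glucose replicate 1 (adjusted p = 0.0607) and with only the 2 groups in the fit. Glutathione S-transferases had 5 of 26 lower and 1 higher (5 and 1 adjusted over the list alone, 4 and 2 after median centring or without glucose replicate 2, 5 and 0 without glucose replicate 3, and 4 and 0 without pine replicate 1). Catalase 84844 stood at 814 ± 38.3 RPKM (-1.88, SE 0.38) as 1 of 3 antioxidant genes that fell and 1 that rose among 28. These became 1 and 1 without glucose replicate 1, and 2 and 2 after median centring or without glucose replicate 2 or 3 or pine replicate 3. Isocitrate lyase and phosphorylmutase family model 92053, whose activity the label does not settle, fell from 1361 ± 1010 to 191 ± 165 RPKM (-3.51, SE 0.96, adjusted p = 0.0197). That call was lost without glucose replicate 1 (adjusted p = 0.0782) and with only the 2 groups in the fit. Cytochrome P450 genes had 25 of 181 higher and 21 lower (25 and 23 adjusted over the list alone). Peptidases had 5 of 233 higher and 15 lower (8 and 14 after median centring), and transcription factors 4 of 189 higher and 10 lower (4 and 8 adjusted over the list alone, and 5 and 8 after median centring). Terpene synthase 120409 rose by 2.84 (SE 0.25) and terpenoid synthase 162429 fell by 2.94 (SE 0.3), as 2 of 34 higher and 3 lower (2 and 2 after median centring). Peroxide-generating oxidases had 3 of 17 higher and 1 lower (3 and 0 without glucose replicate 2 or pine replicate 2), and lipases 2 of 27 higher and 1 lower (2 and 0 after median centring or without glucose replicate 1 or 3, aspen replicate 1 or 3 or pine replicate 2). The replication and cell cycle list had 2 of 43 higher, cyclin-like 163204 and cyclin 49361 (1 without glucose replicate 3 or pine replicate 2). The heat shock list had 1 of 73 lower, heat shock factor-type DNA-binding protein 100521. The called members of the heat shock list numbered 0 and 2 without glucose replicates 1 and 2, 2 without aspen replicate 2 or 3, and 4 without pine replicate 1, and after median centring 1 was higher and 1 lower. Chloroperoxidase 127787 fell by 1.76 (adjusted p = 0.0492), a call lost in 15 of 21 alternatives, 9 of them without glucose replicate 1 or 2, Avicel replicate 2 or any 1 wood library (highest adjusted p = 0.169). No proteasome gene among 33 was called by limma, where 12 had an unadjusted p under 0.05.

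Pine and aspen, compared within lane 2, differed at 16 genes, 14 higher and 2 lower on pine. The largest difference was in cytochrome P450 99035, at 10.5 ± 5.04 RPKM on aspen and 106 ± 54.5 on pine (log2 change 3.16, SE 0.47, adjusted p = 0.0209). P450 24177, about 10 kb away on scaffold 3 (3473672 to 3476193 against 3483874 to 3486215), stood at 6.82 ± 0.839 and 58.8 ± 23.3 (2.85, SE 0.29, adjusted p = 0.00256). Dihydrodipicolinate synthetase 104457 was higher on pine at 112 ± 30.7 against 27.3 ± 3.7 RPKM (1.97, SE 0.19, adjusted p = 0.00256), and GH28 92023 at 14 ± 3.27 against 3.94 ± 0.295 (1.58, SE 0.17). P450 136784 was lower on pine at 55.4 ± 14.8 against 157 ± 19.6 RPKM (-1.51, SE 0.21), as was unlabelled 68457 (-1.78, SE 0.28). The call on 99035 was lost without aspen replicate 1 or 3 or pine replicate 2 or 3 (highest adjusted p = 0.101), that on 136784 without aspen replicate 2 or 3 (highest 0.096), and that on 68457 in 9 of 21 alternatives (highest 0.15). With only these groups in the fit 99035, 136784 and GH28 92023 were not called. The comparison asks how a softwood and a hardwood differ as substrates.

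Sugar transporters 163632, 135536 and 146824 stood at 117 ± 24.5, 385 ± 98.5 and 7.72 ± 1.32 RPKM on pine against 43.3 ± 5.98, 166 ± 9.47 and 3.17 ± 0.141 on aspen, as 3 of 26, or 4 adjusted over the list alone (camera adjusted p = 0.000228, and adjusted p = 0.173 with an estimated correlation). None was called without any 1 of the aspen libraries, without pine replicate 2 or with only these groups in the fit, and 163632 lost its call in 12 of 21 alternatives. For pectinases 1 of 17 was higher, or 5 adjusted over the list alone (camera adjusted p = 3.12e-07, and adjusted p = 0.173 with an estimated correlation), and 2 and 3 were called without pine replicates 1 and 3. For cytochrome P450 genes 3 of 181 were higher and 1 lower, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0416, and adjusted p = 0.765 with an estimated correlation). The called numbers were 1 and 1, 2 and 0, and 1 and 0 without aspen replicates 1, 2 and 3, and 1 and 1 without pine replicate 3. For beta-glucosidases limma called none of 9, over all genes or over the list alone, where 5 had an unadjusted p under 0.05. GH3 29607, chosen after its values were seen, had a limma adjusted p of 0.0285 but missed the fold threshold (log2 change 0.84). The camera adjusted p was 5.98e-05, with adjusted p = 0.173 with an estimated correlation. Antioxidant genes had none of 28 called by limma (6 with an unadjusted p under 0.05) and a camera adjusted p of 0.00151 upward, with adjusted p = 0.153 with an estimated correlation. Dienelactone hydrolase 141329 (1.96, adjusted p = 0.0405) and P450 104855 (1.89, adjusted p = 0.0475) lost their calls in 14 and 15 of 21 alternatives. Without aspen replicates 1, 2 and 3 the count of called genes was 6, 6 and 4, and with only these groups in the fit it was 9.

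**Figure D3:**
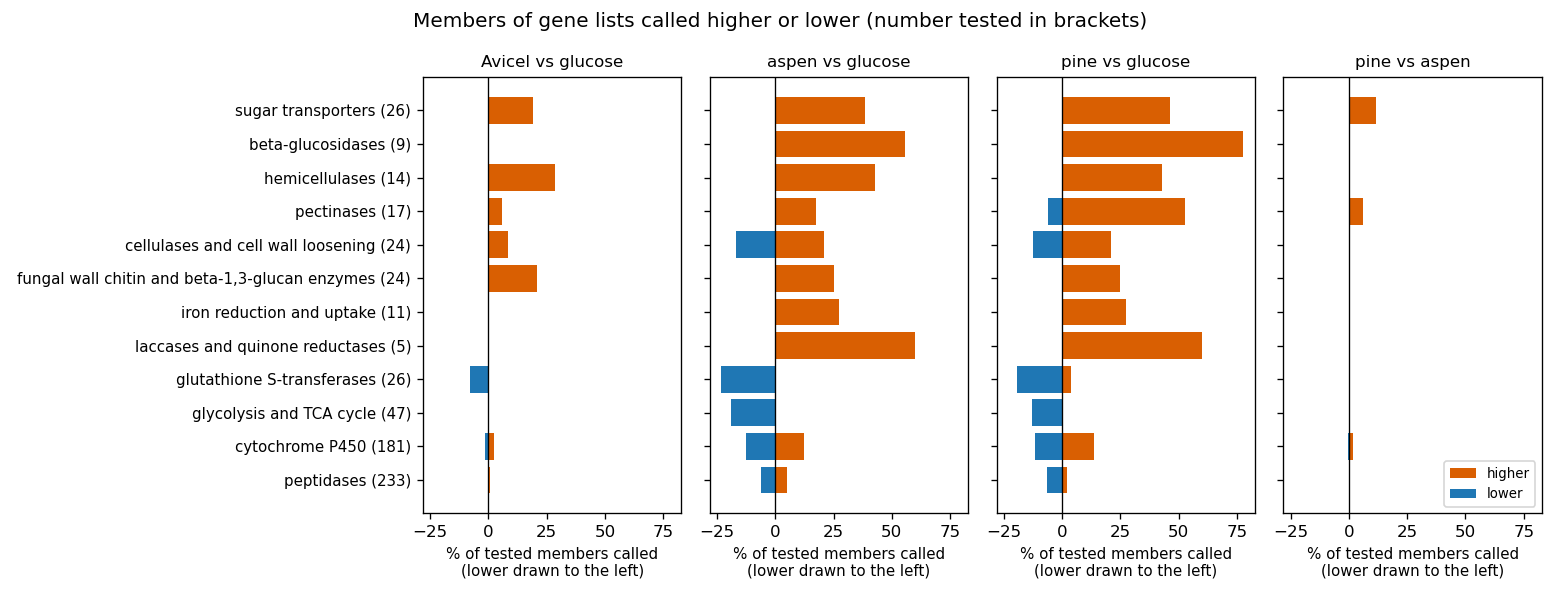
Percentage of tested members of 12 gene lists called higher (orange, right of 0) or lower (blue, left of 0) by limma, in Avicel, aspen and pine against glucose and in pine against aspen, with the number of tested members in brackets. Beta-glucosidases had 5 of 9 members higher on aspen and 7 of 9 on pine, and glutathione S-transferases had 6 and 5 of 26 lower.

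Each wood also differed from crystalline cellulose. On aspen 357 genes were higher and 379 lower than on Avicel, and on pine 464 were higher and 455 lower. After median centring these were 311 and 434, and 408 and 520, after quantile normalization 344 and 388, and 445 and 473, and without a fold threshold 1025 and 636, and 1185 and 795. Without Avicel replicates 1, 2 and 3 they were 390 and 496, 363 and 332, and 293 and 271 on aspen, and 493 and 542, 460 and 368, and 411 and 361 on pine. Neither balance has a settled direction. Unlabelled 129955 showed the largest rise on aspen, from 1.24 ± 0.365 to 221 ± 25.8 RPKM (log2 change 6.64, SE 0.26), with major facilitator 166774 from 3.71 ± 0.763 to 72.9 ± 18.3 (3.96, SE 0.23). Lower on aspen were GH5 141870 at 18.3 ± 9.77 against 1247 ± 1150 RPKM (-5.27, SE 0.99), GH12 24190 at 8.1 ± 3.08 against 795 ± 913 (-5.26, SE 1.04) and GH10 110801 at 3.31 ± 1.78 against 206 ± 198 (-4.44, SE 1.09). Avicel values of these 3 genes were 95.8, 1247 and 2397, then 38.5, 537 and 1809, then 6.94, 209 and 402 RPKM in replicates 1, 2 and 3. The call on 110801 was lost without Avicel replicate 2 or 3 or aspen replicate 3 (highest adjusted p = 0.0697) and with only the 2 groups in the fit.

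On pine against Avicel, multicopper oxidase 157228 rose from 1.92 ± 0.471 to 104 ± 94.7 RPKM (4.79, SE 0.56), and 4 of 5 members of that family were higher (Fisher adjusted p = 0.00346). That number was 2 without any 1 glucose library, Avicel replicate 1 or 3, aspen replicate 1 or pine replicate 1. It was as low as 2 under another planned setting. Peptidase A1 22529 (-5.11, SE 0.34), epoxide hydrolase-like 134844 (-4.84, SE 0.39) and unlabelled 18691, at 22.5 ± 6.66 against 1648 ± 605 RPKM (-6.10, SE 0.59), were lower. TauD/TfdA dioxygenases were higher for 5 of 8 members (chance 0.37, adjusted p = 0.00192). These comparisons cross lanes, so lane and medium cannot be told apart within them.

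Called genes were shared between the comparisons with glucose. Aspen and pine shared 425 higher and 513 lower genes, where independent lists would share 29.9 and 41.4 (157 and 140 shared at a fold of 4), and no gene was called in opposite directions. Avicel shared 83 higher and 65 lower genes with aspen (independent lists 5.1 and 4.7) and 74 and 61 with pine (5.5 and 4.5), with 1 and 3 genes in opposite directions. In 100 simulations of unchanged groups that shared the glucose libraries, 0 calls were shared on average. With no gene changed, hardly any gene can pass in a comparison. That count therefore cannot show what the shared libraries add to these overlaps. The log2 changes correlated across genes at 0.573 for Avicel and aspen, 0.518 for Avicel and pine and 0.928 for aspen and pine, where simulated unchanged groups gave 0.498, 0.499 and 0.499. The covariance exceeded the simulated one of 0.031 by 0.176, 0.165 and 0.62. The 3 glucose libraries are too few to split, so part of each excess may come from the shared controls. In all, 73 genes were higher and 60 lower on Avicel, aspen and pine alike, among them 72733 and 102298.

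The authors' deposited table lists 666 models with p under 0.05 for Avicel against glucose, 2936 for aspen, 2645 for pine and 197 for pine against aspen, with no fold threshold. Of the genes called here, 162 of 170, 1173 of 1202, 1110 of 1202 and 16 of 16 also had a p under 0.05 in the authors' deposited table. The direction was the same for every called gene for which the authors' deposited table gives a ratio.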

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

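Of the tests in this part, the count of genes called on Avicel, aspen and pine alike and the test of neighbours with different InterPro labels were chosen after results were seen.

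The deposited table also holds protein scores that the comparisons above did not use. An emPAI score above 0 was listed on a carbon source, with 0 on glucose, for 26 proteins on Avicel, 216 on aspen and 166 on pine. These are single values per carbon source, without replicates, and 704 proteins had a score on at least 1 carbon source. By carbon source, 436 had a score on glucose, 252 on Avicel, 580 on aspen and 513 on pine. GH18 146767 had scores of 0, 0.636, 7.06 and 4.8 on glucose, Avicel, aspen and pine, and GH5 139561 of 0, 0, 0.772 and 0.599. Peptidase A1 22529, with lower transcripts on wood, scored 12, 12.1, 0.744 and 0.846.

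Wood against glucose crosses the sequencing lanes, so a lane effect was weighed as the source of the changes shared by aspen and pine. Within lane 1, 133 genes were called on Avicel against glucose in the same direction as on both woods, where simulations with Avicel equal to glucose gave at most 1. With Avicel set equal to glucose for every gene, hardly any gene can pass on Avicel. That simulated count was therefore near 0 in advance, and no conclusion is drawn from it. A further 1 of the genes called alike on both woods was called in the opposite direction on Avicel. Of the 804 not called on Avicel, the median Avicel change, signed by the wood direction, was 0.46, with 83.6% on the same side, where the simulations gave at most 0.08. A lane effect would leave Avicel at glucose, so this signed median argues against lane as the whole cause for the 804 genes as a set. For any single gene called on wood alone, lane and medium cannot be told apart, because each lane holds only its own media.

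Avicel replicate 1 had low transcripts of GH5 141870, GH10 110801 and GH12 24190 (95.8, 6.94 and 38.5 RPKM) beside replicates 2 and 3 (1247 and 2397, 209 and 402, 537 and 1809). Over 164 genes that separate glucose from the other Avicel libraries, it lay at a median of 0.83 on a scale from glucose at 0 to Avicel at 1, with quartiles of 0.17 and 1.15 and resampled medians of 0.6 to 0.94, which argues against a mislabelled glucose library. Over 714 genes that separate the other Avicel libraries from wood, it lay at 0.29 of the way to wood (0.26 to 0.32), which argues against a mislabelled wood library. A mixed sample or a culture in another state stays open, and no biological explanation was tested.

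In the order of the 10184 tested models along each scaffold, genes called alike on both woods lay side by side more often than shuffled calls. Models that were not tested were skipped, so some may lie between the models of a pair. There were 134 adjacent pairs called in the same direction, 44 higher and 90 lower, where 10000 shuffles gave a mean of 43.1 and at most 73 (permutation p = 0.0001, the smallest they can give). Reads shared by overlapping models are argued against as the whole cause, since 118 pairs that do not overlap were left against a shuffled mean of 38.7. Without pairs that share an InterPro label 125 were left against 42.1, but 94 of these hold a model without a label, so tandem copies of a family stay open for them. Of the called pairs in which both models carry a label, 29 differed in the label and in its first word. Calls shuffled among labelled models gave a mean of 15.1 (permutation p = 0.0009), which argues against tandem copies as the whole cause for labelled pairs. Overlapping models were kept in that test, so shared reads stay open for those labelled pairs. That co-located genes change together on wood is a hypothesis, found and tested on the same data, and shared chromatin state or a common regulator was not tested. Whether some adjacent models are parts of a single gene, which would count that gene more than once, was not tested either.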

How the results depend on the processing

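The counts of called list members without each library were added after seeing the data, and every other alternative was planned. Without a fold threshold, 315 genes were called for Avicel, 2689 for aspen and 2736 for pine against glucose, and 1661 and 1980 for aspen and pine against Avicel. At a fold of 4 these were 39, 364, 403, 208 and 281, with 2 for pine against aspen, and the overlaps were 33 (Avicel and aspen), 31 (Avicel and pine) and 297 (aspen and pine). These follow from the thresholds themselves. With only the 2 groups in the fit, pine against aspen had 9 genes, 5 of them among the 16, and the cause was not tested. Leaving out 1 library gave 93 (without glucose replicate 2) to 190 (without Avicel replicate 2) genes for Avicel against glucose. It gave 4 (without aspen replicate 3) to 23 (without glucose replicate 3 or pine replicate 3) for pine against aspen, 1044 to 1226 for aspen and 1073 to 1275 for pine against glucose, 564 to 886 and 772 to 1035 for aspen and pine against Avicel, and 2161 to 2987 for the F test.

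With an estimated correlation, camera passed 0 of 144 pairs of list and comparison (24 at an unadjusted p under 0.05, smallest adjusted p 0.153), against 48 with the preset one (64 unadjusted). The tool fry passed 33 (59 unadjusted), 23 of them shared with camera. The cause was not tested. Median centring ended 1 of the 48 and quantile normalization 4, and no list changed direction under these. Residual correlations overlapped between equal replicate numbers (-0.42 to 0.44, median -0.01) and different numbers (-0.42 to 0.33, median -0.04). The highest, 0.437, joined replicate 3 of aspen and of pine, and pairing by number was not tested. A replicate block gave 175, 1230, 1230, 21, 779 and 944 genes in the 6 comparisons, 2781 in the F test and 51 list pairs. Over the named genes, 3684 values under an alternative kept the call, 316 lost it and 0 changed direction, and 11 were not tested under the minimum of 10 RPKM. Depth limits genes below 0.13 to 0.2 RPKM for a model of 1 kb.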

Other observations

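The test of signal peptides among models with a deposited probability was chosen after results were seen, the other tests of hypotheses were planned, and the genes of the runs below were chosen after their values were seen.

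Runs of 4 models, adjacent in the order of tested models and all lower on both woods than on glucose, lay on 5 scaffolds. Untested models may lie between them. On scaffold 13, at 131012 to 183539, unlabelled 28164 stood at 7278 ± 2670 RPKM on glucose, 1484 ± 441 on aspen and 1969 ± 240 on pine, and its neighbour 28176 at 4035 ± 1340, 1175 ± 384 and 1366 ± 250. Protein kinase-like 145980 in the same run fell by 1.57 on aspen and 1.61 on pine. On scaffold 8, at 106347 to 130630, GATA factor 133057 (log2 changes -2.31 on aspen and -2.63 on pine) and EF-hand protein 138753 (-1.65 and -1.58) were members. On scaffold 2, at 3852943 to 3863132, cytochrome P450 models 97657, 64378 and 97658 flanked peptidase M1 88250, which fell by 1.44 on aspen. Models 97657 and 64378 lie on the same strand, at 3852943 to 3853944 and 3853992 to 3854377. Whether these P450 models are parts of a single gene was not tested. Model 64378 stood at 0.086 RPKM on aspen and 0.11 on pine, below the floor of 0.13 to 0.2 RPKM for a model of 1 kb. The remaining runs were on scaffold 3 at 1536074 to 1545902 and on scaffold 5 at 2817317 to 2821209. The 4 models of the scaffold 5 run lie on the same strand, with means of 7.62 to 10.8 RPKM on glucose. Whether these 4 models are parts of a single gene was not tested.

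For GH12 24190 the emPAI scores were 15.5, 34.6, 10.3 and 8.98 on glucose, Avicel, aspen and pine, with transcripts at 218 ± 96.6, 795 ± 913, 8.1 ± 3.08 and 17.4 ± 11.3 RPKM. The Avicel transcript did not pass against glucose (log2 change 0.73, SE 1.04), with replicate 1, at 38.5 RPKM, below every glucose value. The most abundant Avicel transcript among the named genes, 167658, scored 7.53, 55.7, 4.44 and 14.5. Catalase 84844 scored 3.09, 0.503, 1.01 and 1.26.

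The hypothesis that proteins seen on wood and not on glucose reflect transcript level was tested with a one-sided Fisher test. Of 212 tested proteins with a score on aspen and none on glucose, 36 (17%) had transcripts called higher, against 43 of 476 other detected proteins (9%, Fisher exact p = 0.0024). On pine these were 39 of 166 (23.5%) against 40 of 522 (7.7%, Fisher exact p = 1.7e-07), and on Avicel 1 of 26 against 29 of 662 (p = 0.69). These values are consistent with a contribution of transcript level on wood, although most such proteins had no called rise. The Spearman correlation across genes of the emPAI ratio with the log2 change was 0.37, 0.16 and 0.19 for Avicel, aspen and pine.

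The hypothesis that genes raised on wood encode secreted proteins was tested with the deposited signal peptide probabilities. Of 829 tested models with a probability of at least 0.5, 106 (12.8%) were called higher on both woods, against 319 of 9355 other models (3.4%, Fisher exact p = 4.7e-27). Of the others 9271 have no deposited probability, so that comparison leaves the hypothesis open. Among models with a probability, 4 of 84 below 0.5 (4.8%) were called higher on both woods (Fisher exact p = 0.017). For genes called lower on both woods the shares were 5.7% and 4.8% (Fisher exact p = 0.49). Among models with a probability the values are in line with the hypothesis for the genes that rose.

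Other splits of the libraries were refitted. Each pair of groups has 10 splits, too few for a share under 0.05, and 1 split, the real one, gave as many genes in each comparison. The real and the highest other counts were 170 and 18 for Avicel against glucose, 1202 and 0 for aspen, 1202 and 0 for pine, 16 and 2 for pine against aspen, and 736 and 0 and 919 and 0 for aspen and pine against Avicel. Every other split mixes both groups on each side, which moves a real difference between them into the spread. The low counts of those splits are therefore no measure of noise alone. For the F test, 1 of 100 groupings of the 12 libraries, the real one, gave as many genes (2987, highest other 2011). That share is the smallest that 100 groupings can give, so chance assignment of libraries is argued against for that count and not excluded.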
